A study of Mus musculus with 6 samples.

How the data were processed

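Gene expression was measured in 6 samples of mouse small intestinal organoids, which are epithelial structures grown from intestinal crypts in gel. Per the labels' protocols, organoids came from Villin-Cre mice or from Villin-Cre mice with floxed Snai1 alleles, and had been exposed to 0.5 µM tamoxifen for 24 hours. RNA was extracted with Trizol, cleaned on a column with DNase, amplified to biotin-labelled cRNA and hybridised to Illumina arrays. There were 3 control arrays (Villin-Cre) and 3 Snai1 knockout arrays (Villin-Cre with floxed Snai1), grouped by their titles. The labels do not say whether the 3 arrays of a group came from separate animals, passages or wells, so p-values measure the spread between these samples, which may be technical.

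The deposited table holds values on a log scale, taken here as log2, for 45281 probes on each array. The sorted values of the 6 arrays differed by at most 0.0019, so the authors had equalised the distributions between arrays (quantile normalization) before deposit, and the values were used as deposited. The log base, the background correction and the software are not given in the sources used here. The column medians lay between 7.8736 and 7.8737, and the median lay only 0.163 above the lowest value of 7.71, while the highest was 14.8. Low values are therefore compressed, which is what an added offset or a variance-stabilising transform would do, and fold changes of dim genes are understated by an unknown amount. All folds below assume base 2. The table gives no detection calls, so no probe was called present or absent. The number of arrays, not a read depth, limits the precision. The median standard error of a difference was 0.067 among the 6969 genes whose mean exceeded 8.27, the upper quartile of all values.

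Probes were named through the platform's annotation, which paired 34885 probes with 1 gene and 18 with several. It lists no gene for the other 10378 probes, which are unnamed here. By gene number, 34807 of the 1-gene probes matched the GRCm38.p6 gene table, and no symbol changed. That table was used only for names and for the order of genes along chromosomes. Each gene was represented by the probe with the highest mean over all 6 arrays, which gave 19057 genes. No dim gene was filtered out. Further probes of a gene entered only the fit of all probes and the alternative that averages a gene's probes.

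Knockout was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, Benjamini-Hochberg adjusted p under 0.05 over all genes). A set of 28 gene lists covering organoid lineages, signalling, stress, metabolism and other cell types was written before the data were examined, as were the tests of genes and lists and all alternatives except 3. Of the lists' 693 symbols, 630 were measured. The others, among them Mki67, were not analysed here. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 28 lists, and again with a correlation estimated from the arrays and with fry. Camera compares a list with all other genes, while fry tests only whether a list's own genes move one way or, in its mixed form, in either direction. Counts of members are given over all genes and adjusted over the list alone.

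The genes named are 15 fixed beforehand, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, or all of them where fewer, and, in each list described, the 4 members of lowest p. Others are marked as chosen after their values were seen.

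Both groups carry replicate numbers 1 to 3. Deviations from the group means, correlated over all genes, gave r = 0.35 for replicates numbered 1, 0.33 for those numbered 2 and 0.46 for those numbered 3, and each array correlated best with the array of its own number. The numbers were therefore treated as pairing the samples in the blocked fit and in the counts of pairs. The labels do not state what a number shares. The main fit, fixed in advance, had no block, and the blocked value is printed where it changes a call. The blocked fit leaves fewer residual degrees of freedom.

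In simulated data with the real genes' means and variances and 200 changed genes drawn from those above the upper quartile, the limma test recovered 88.1% of 67 genes changed by 0.5 on the log2 scale, 100% of 67 changed by 1 and 100% of 66 changed by 2. Of all its calls, 7.69% were unchanged genes. Camera recovered a list shifted by 1 standard deviation and called no other. Variances were limma's moderated ones, and genes were drawn independently, without correlation between genes or any replicate structure. The simulation therefore does not show how often camera calls unshifted lists in the real data. Alternatives covered the replicate block, normalization, filters on dim probes, the handling of several probes per gene, the variance model, array weights, a fold threshold, the list test and leaving out each array. A floor before taking logs was not tried, because the table was already on a log scale. Figures were drawn with matplotlib 3.10.9.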

Results

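Transcripts were profiled in small intestinal organoids that had been exposed to 0.5 µM tamoxifen for 24 hours, 3 samples from mice with the Villin-Cre transgene alone (control) and 3 from mice that also carried floxed Snai1 alleles (Snai1 knockout). Cre driven by the Villin promoter acts in the intestinal epithelium, and Snai1 encodes a zinc-finger repressor best known from epithelial-mesenchymal transition (EMT). The comparison asks, by the series title, how Snai1 bears on lineage allocation and on the maintenance of stem cells. Each array gave 45281 values with the same distribution, and arrays correlated with each other at r = 0.994 to 0.997 over all probes. The first principal component, with 34.95% of the variance, placed the control arrays at -9.52, -4.79 and -1.08 and the knockout arrays at 0.43, 5.33 and 9.63. On the second, with 24.46%, control replicates 1 to 3 lay at 5.43, -6.27 and -0.55. Knockout replicates 1 to 3 lay at 7.89, -5.79 and -0.71, so arrays of the same replicate number lay near each other.

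Snai1 itself was not measurably different. Its brighter probe, ILMN_2904765, read 7.91 ± 0.04 on control arrays and 7.91 ± 0.05 on knockout arrays (log2, SD, n = 3 each; exact permutation p = 0.9, smallest possible 0.1). Its other probe, ILMN_1241355, read 7.86 ± 0.03 and 7.87 ± 0.04 (exact permutation p = 0.6). These levels were brighter than 59.1% and 49.1% of all probes, on an array whose median was 7.87. At such levels a loss of the transcript was not detectable, and whether either probe lies in the deleted part is not given in the sources used here. The Snai1 probes therefore do not check the labels.

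Between knockout and control, 25 of 19057 genes changed, 7 higher and 18 lower, and for all 25 the 3 knockout values lay on the same side of the 3 control values. Erdr1, a gene of the pseudoautosomal region, rose most, from 7.94 ± 0.04 to 11.9 ± 0.23 (log2, SD, n = 3), 15.6-fold on the deposited scale (adjusted p = 0.00037, limma). Its control values sat near the bottom of the scale, where values are compressed. Esrp1, an epithelial splicing regulator, rose 2.39-fold, with a log2 difference of 1.26 ± 0.07 (SE; adjusted p = 0.0062). Sema5a, a semaphorin, rose 1.74-fold, and Ctse, which encodes the protease cathepsin E, rose 1.71-fold from an already bright 11.9. The inositol phosphate kinase gene Ip6k2 rose 1.52-fold from 7.94, also near the bottom of the scale, Tmem254a 1.44-fold and Ckap2, a microtubule-associated gene, 1.16-fold.

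Among the genes tested by their brightest probe, Serinc3, a membrane protein gene, had the largest measured fall, from 11.4 ± 0.11 to 9.92 ± 0.11, so control exceeded knockout 2.82-fold (adjusted p = 0.0062). Prkag2, a regulatory subunit of AMP-activated kinase, was 2.04-fold higher in control (log2 difference -1.03 ± 0.03, SE; adjusted p = 0.00037), and Pdrg1 1.97-fold. Both fell to 7.93 ± 0.04 and 7.81 ± 0.04 on knockout arrays, close to the median of all probes, where values are compressed and falls understated. Ahcy, which hydrolyses S-adenosylhomocysteine in the methionine cycle, was 1.85-fold higher in control, and Paip1, a translation factor that binds poly(A)-binding protein, 1.84-fold. Further falls were those of Cmbl (1.74-fold higher in control), Sgip1 and the semaphorin gene Sema7a (1.61-fold each), 1500035N22Rik (1.53-fold, to 7.83 ± 0.01, at the compressed end of the scale, so its fall is understated), the aldo-keto reductase gene Akr1b8 (1.52-fold), the ATP synthase subunit gene Atp5e (1.49-fold) and the insulin-like gene Insl6 (1.48-fold). Of the named falls, Serinc3, Pdrg1, Ahcy and Atp5e lie on the chromosome that carries Snai1 in GRCm38.p6. On other chromosomes, Prkag2 lies within 30 measured genes of 1500035N22Rik, and Sema5a within 30 of Cmbl.

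**Figure D1:**
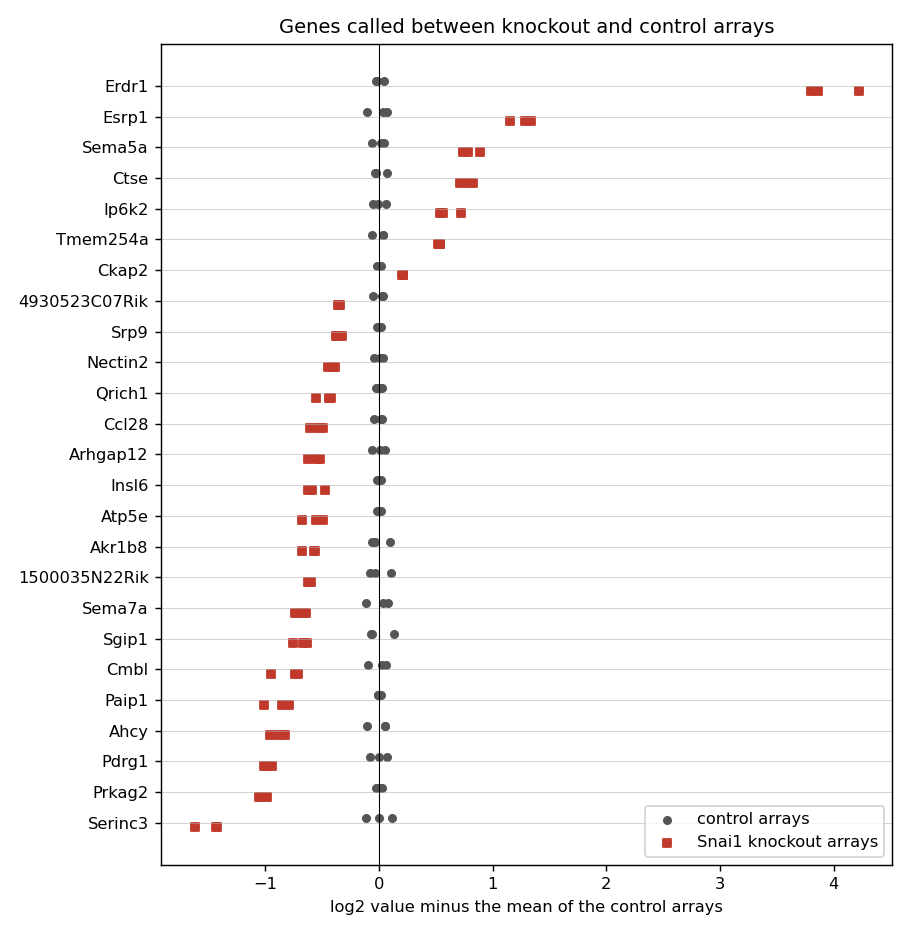
Each line is 1 of the 25 genes called at an adjusted p under 0.05. The horizontal axis is the log2 value of an array minus the mean of the 3 control arrays, with circles for control and squares for knockout arrays; Erdr1 lies farthest to the right, with a mean difference of 3.96, and Serinc3 farthest to the left, at -1.49.

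At an unadjusted p under 0.05 there were 1376 genes, 739 higher and 637 lower, where 953 would be expected by chance, and 12.05% of all genes had groups that did not overlap, against 10% by chance. With the replicate number as a block, 9 genes remained, all among the 25: Erdr1, Esrp1, Sema5a, Ctse and Ip6k2 higher, and Serinc3, Prkag2, Pdrg1 and Sema7a lower. The blocked adjusted p of the other 16 ran from 0.051 for Ahcy to 0.13 for Ckap2, with Tmem254a at 0.056, Paip1 at 0.057, Akr1b8 at 0.063, 1500035N22Rik and Sgip1 at 0.069, Insl6 at 0.070, Atp5e at 0.072 and Cmbl at 0.085. The count was 6 without control replicate 1, 15 without control replicate 2, 9 without control replicate 3, 13 without knockout replicate 2 and 4 without knockout replicate 3.

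The list of p53 targets and apoptosis genes was higher in the knockout by camera's test (adjusted p = 0.00036, and 8.2e-05 with the replicate block). This call was lost with a correlation estimated from the arrays (adjusted p = 0.72, unadjusted 0.053) and with fry (adjusted p = 0.15, unadjusted 0.0053). In these 2 settings none of the 28 lists passed. The call was also lost with camera on ranks, a setting added after seeing the data (adjusted p = 0.059). In 1 of the 9 other splits of the arrays into groups of 3 the list also passed (adjusted p = 0.0084). Of its 30 measured members 20 were higher and 10 lower, the mean log2 difference was 0.106 and the median 0.034, and the list's mean was higher in 3 of 3 pairs of the same number (0.116, 0.0996 and 0.103). Only Ckap2 passed over all genes, by 0.21 ± 0.02 (SE), while 7 members rose adjusted over the list alone and none fell. With the replicate block 8 rose, these 7 and Bbc3. Of these 7, Trp53inp1 differed by 0.55 ± 0.07 (adjusted p = 0.11 over all genes), the cell cycle inhibitor Cdkn1a (p21) by 0.39 ± 0.06 (adjusted p = 0.14) and Ccng1, which encodes cyclin G1, by 0.46 ± 0.11 (adjusted p = 0.34). The other 3, named after their values were seen, were Mdm2, the ubiquitin ligase for p53, at 0.27, Phlda3 at 0.34 and Zmat3 at 0.39. No other member passed adjusted over the list alone without the block. Among these, likewise named afterwards, Bbc3 (Puma), which promotes apoptosis, differed by 0.23 ± 0.08 (SE) and was higher in 3 of 3 pairs (adjusted p over the list alone 0.069, and 0.0024 with the block), Ei24 differed by 0.15, the survival gene Mcl1 by 0.13 and Bak1 by -0.06.

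Fry's test for change in either direction passed for this list (adjusted p = 0.0036). Trp53inp1 lies within 30 measured genes of the called gene Esrp1.

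**Figure D2:**
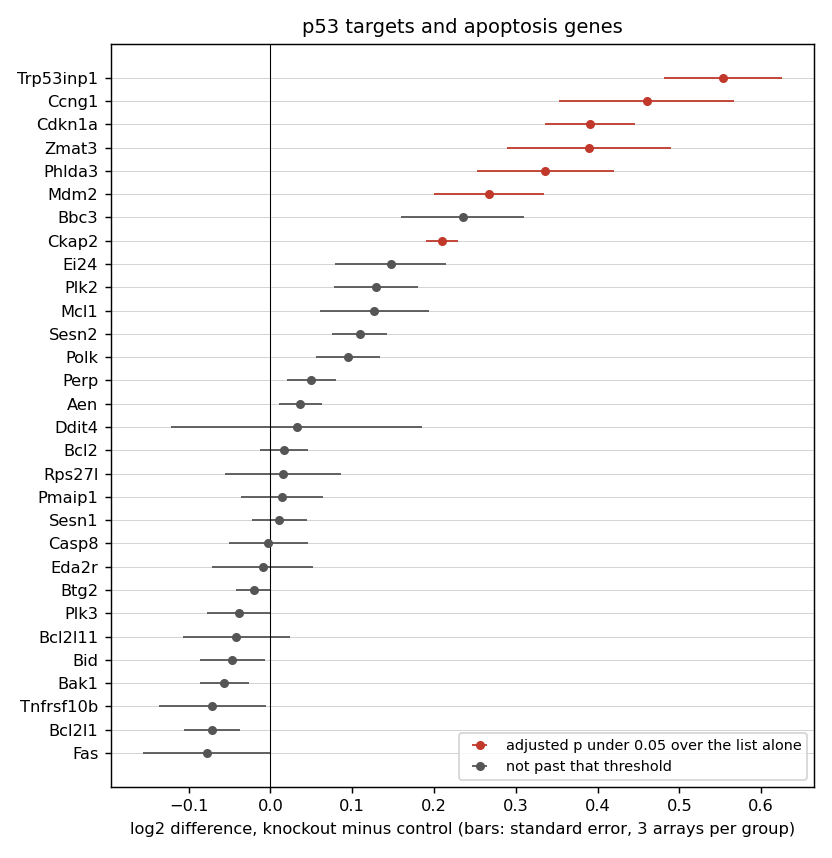
Log2 differences, knockout minus control, of the 30 measured p53 targets and apoptosis genes, with standard errors as bars (3 arrays per group). Red marks the 7 genes past an adjusted p of 0.05 over the list alone, all of them higher in the knockout, led by Trp53inp1 at 0.55.

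Markers of crypt base stem cells were also higher in the knockout arrays by camera's test (adjusted p = 0.00098). The call was lost with an estimated correlation (adjusted p = 0.72, unadjusted 0.19) and with fry (adjusted p = 0.69, unadjusted 0.21), settings in which no list passed. It was also lost without knockout replicate 2 (camera adjusted p = 0.077). The list also passed in 3 of the 9 other splits of the arrays, which mix the genotypes (adjusted p = 3.2e-11, 0.0058 and 0.033). Of 25 measured members, 21 had a higher mean, the mean log2 difference was 0.120 and the median 0.080, and the list's mean was higher in 3 of 3 pairs, but by unequal amounts of 0.0529, 0.0835 and 0.222. No member passed over all genes or, without the block, adjusted over the list alone. With the replicate block, 3 members rose adjusted over the list alone, Lgr5 (adjusted p = 0.0023), Axin2 (0.021) and Nav1 (0.032), and 1 fell, Igfbp4 (0.021), the last named after its values were seen. Olfm4, an abundant stem cell transcript, differed by 0.45 ± 0.13 (SE; 10.5 ± 0.20 in control against 10.9 ± 0.19, SD, n = 3; adjusted p = 0.48). Lgr5, the receptor that marks these cells, differed by 0.42 ± 0.18 (adjusted p = 0.73; blocked SE 0.03), while the stem cell transcription factor Ascl2 read 8.54 ± 0.11 and 8.58 ± 0.07. Nav1 differed by 0.27, Clca3b, whose probe may see related Clca genes, by 0.33, and Gkn3 by -0.08.

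Wnt targets, which share 9 of their 24 measured genes with the stem cell list, had a mean difference of 0.056 (camera adjusted p = 0.21, and 0.033 with the replicate block, but 0.67 with block and estimated correlation). With the block, Lgr5 and Axin2 rose adjusted over this list alone as well (adjusted p = 0.0022 and 0.023). Axin2, a feedback inhibitor of Wnt signalling, differed by 0.28 ± 0.13 (SE), Cd44 by 0.12 and Lef1, at 7.86 in control, by -0.06. In the list of reserve or +4 stem cell genes, 6 of 7 members had a higher mean and none passed. Hopx differed by 0.21, Lrig1 by 0.21, Bmi1 by 0.07 and Mex3a by 0.04 (list adjusted p = 0.064 with camera).

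Among differentiated lineages no marker passed over all genes or, without the replicate block, adjusted over its list alone. Enterocyte genes were lower on average, with 22 of 32 members lower and a mean difference of -0.075. Examples were the amino acid transporter Slc7a9 (-0.43), the apolipoproteins Apoa1 (-0.28) and Apoc3 (-0.25), and Dgat1 (-0.21), which makes triglyceride. Alpi, the brush border phosphatase, read 10.98 ± 0.34 in control and 10.75 ± 0.38 in knockout arrays. The enterocyte list did not pass camera's test (adjusted p = 0.068), passed it with the replicate block (adjusted p = 0.015) and did not with block and estimated correlation (adjusted p = 0.67). With the block, 3 members fell adjusted over the list alone, Slc7a9 (adjusted p = 0.021), Apoa1 (0.023) and Rbp2, named after its values were seen (-0.21, 0.013). The list's mean was higher in 1 of the 3 pairs.

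Paneth cell genes showed no common direction, 11 of 21 being higher. Lyz1, the lysozyme of Paneth cells, read 14.55 ± 0.02 on control and 14.45 ± 0.05 on knockout arrays, near the top of the scale, with a difference of -0.10 ± 0.03 (SE; adjusted p = 0.52). Kit differed by 0.16, Clps, a pancreatic-type colipase, by -0.31 and Fzd5 by 0.16, and with the block these 3 passed adjusted over the list alone (adjusted p = 0.033 each). The goblet cell list had 11 of 20 members higher. The mucin gene Muc2 differed by 0.29 ± 0.29, Guca2a by 0.21, Foxa3 by 0.15, Sytl2 by 0.14 and Spdef by 0.11. Of 31 enteroendocrine genes, 16 were lower. Chga, the granule protein chromogranin A, differed by -0.17 ± 0.04 (adjusted p = 0.39), Ghrl, which encodes ghrelin, by -0.29, Sct (secretin) by -0.15 and Tph1 by -0.06, while the progenitor factor Neurog3 differed by 0.07 ± 0.08. Tuft cell genes were mostly dim, and Dclk1 differed by 0.08 ± 0.05 (SE). Avil differed by 0.06, Espn by 0.08 and Gng13 by 0.08. Adjusted p with camera was 0.80 for the Paneth, 0.37 for the goblet, 0.37 for the enteroendocrine and 0.44 for the tuft cell list.

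Notch pathway genes, which govern the choice between absorptive and secretory fates, did not pass camera's test (mean difference 0.018, adjusted p = 0.49). The list's mean was higher in 3 of 3 pairs (0.020, 0.026 and 0.0089). Such agreement was common among lists that did not pass, with tuft cell genes higher in 3 of 3 pairs and enteroendocrine genes in 0. Hes1, a Notch target, read 10.2 ± 0.13 and 10.3 ± 0.05, and Atoh1, which specifies secretory cells, was at 7.79 in both groups, at the bottom of the scale. Dll1 differed by 0.09, Notch1 by 0.17, Rfng by 0.08 and Hes7 by -0.09. In the cell cycle list, 19 of 36 members were higher and 17 lower, the median difference was 0.004 and the mean -0.012, so these differed in sign (adjusted p = 0.82, direction lower). Tyms, which makes thymidylate, differed by -0.18, Birc5 (survivin) by -0.18, Ube2c by -0.13 and Kif11 by 0.14.

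**Figure D3:**
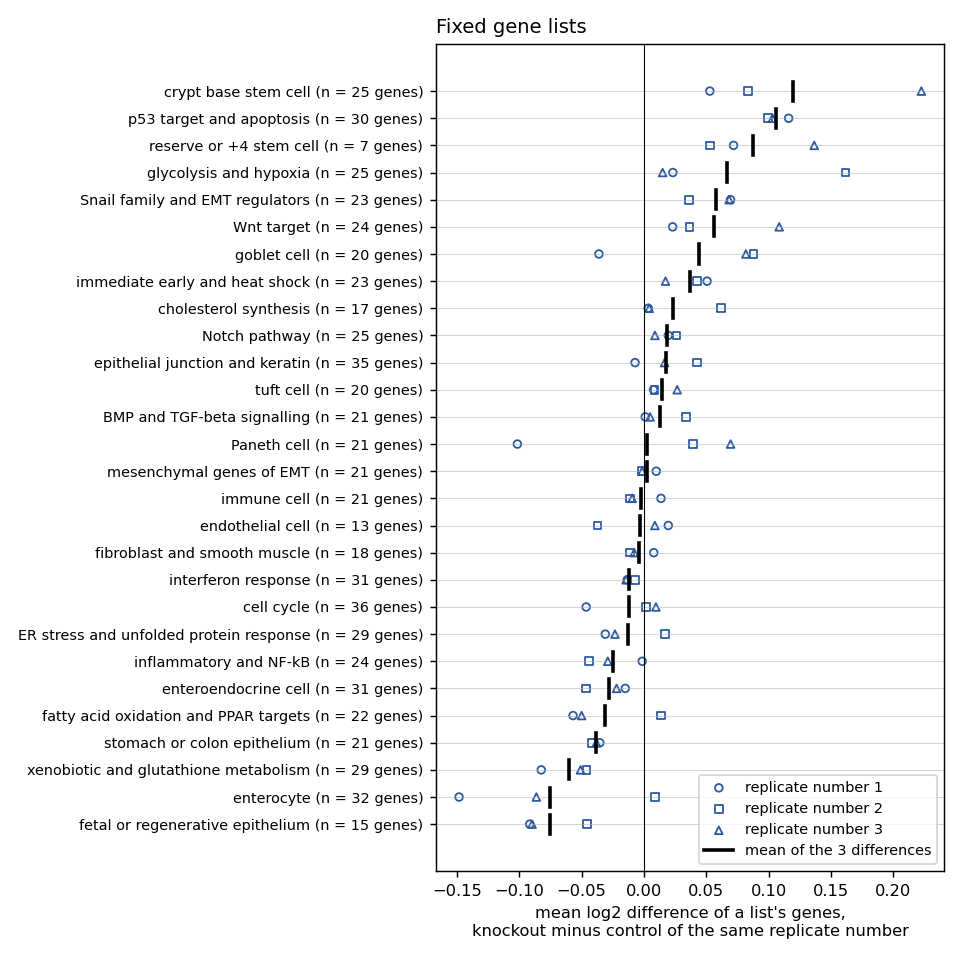
Mean log2 difference of the measured genes of each of the 28 lists. Open symbols are the 3 differences between a knockout and a control array of the same replicate number, black bars are their means, and the p53 list's 3 differences lie between 0.0996 and 0.116, while those of the stem cell list run from 0.0529 to 0.222.

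In the list of Snail family members and EMT regulators, Esrp1 rose and no other member passed. Snai3 differed by 0.13, and Elf3 and Klf5, both epithelial transcription factors, by 0.26 and 0.11. The list as a whole did not pass camera's test (adjusted p = 0.44), with 12 of 23 members higher, 11 lower and a median difference of 0.005. Its mean difference of 0.058, higher in 3 of 3 pairs, includes Esrp1 at 1.26. Fry found change in either direction (adjusted p = 0.0004). That test also includes Esrp1, so it does not show that other members changed. None of 35 epithelial junction and keratin genes passed. Cdh1, the E-cadherin gene and a textbook target of Snail repression, read 11.3 ± 0.20 in control and 11.5 ± 0.33 in knockout arrays, a difference of 0.18 ± 0.18 (SE; adjusted p = 0.94). Llgl2 differed by 0.16, Ctnna1 by 0.13, Cldn3 by -0.13 and Pard6b by -0.05. Mesenchymal genes of EMT were mostly at the bottom of the scale, with a median level of 7.90, and none passed, with Pdgfb at 0.09, Itgb3 at 0.10, Ccn2 at -0.09 and Mmp14 at -0.10. Adjusted p with camera was 0.53 for the junction and 0.93 for the mesenchymal list.

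Several stress and metabolic lists did not pass camera's test as fitted but passed with the replicate block. None of them passed with block and estimated correlation (adjusted p = 0.67 or 0.69), a setting in which none of the 28 lists passed. Lower in this sense were xenobiotic and glutathione metabolism (adjusted p = 0.061 without and 0.033 with the block), with Slc7a11, the cystine transporter, at -0.29, Gsta3 and Gsta4, glutathione transferases whose probes may see related genes, at -0.31 and -0.18, and Srxn1 at -0.16. Genes of fetal or regenerative epithelium were likewise lower (0.058 and 0.004), with Anxa3 at -0.48, S100a6 at -0.22 and Basp1 at -0.04. Higher were immediate early and heat shock genes (0.086 and 0.042), with Egr1 at 0.19, Dusp1 at 0.14, Gadd45a at 0.11 and Hspa1b at 0.05, and glycolysis and hypoxia genes (0.17 and 0.042), with P4ha1 at 0.14, Slc2a1, the glucose transporter, at 0.22, Hk1 at 0.06 and Pkm at 0.08. No member of these 4 lists passed over all genes or, without the block, adjusted over its list alone. With the block and adjusted over the list alone, 4 xenobiotic genes fell, among them Gsta3 (adjusted p = 0.0048) and Slc7a11 (0.029), as did Anxa3 in the fetal list (0.0024). In the glycolysis list P4ha1 rose (0.033), and of members named after their values were seen Pdk1 rose and Vegfa fell (0.033 each).

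In the list of fatty acid oxidation and PPAR targets, Pparg, a lipid-sensing nuclear receptor, fell by 0.16 adjusted over the list alone, and with the block Acaa1b (-0.20, adjusted p = 0.025) did so too. In the interferon list B2m, the light chain of class I histocompatibility molecules, fell by 0.29 adjusted over the list alone, but not with the block (adjusted p = 0.056). Neither Pparg nor B2m passed over all genes (adjusted p = 0.14 and 0.23). No member passed in the inflammatory list, where Il18 differed by -0.25 and Nfkbia by -0.11, in the unfolded protein response, where the pseudokinase gene Trib3 differed by -0.21 and Sesn2 by 0.11, in cholesterol synthesis, where Sqle differed by 0.12, or in BMP and TGF-beta signalling, where Id3 differed by -0.16 and Bmp7 by -0.10. These lists did not pass camera's test with or without the replicate block. Without it the values were interferon response (adjusted p = 0.44), inflammatory and NF-kB genes (0.44), the unfolded protein response (0.86), cholesterol synthesis (0.44), fatty acid oxidation (0.26), and BMP and TGF-beta signalling (0.44). Markers of cells that could accompany the epithelium were dim, and none passed. Fibroblast and smooth muscle genes had a median level of 7.83 with 0 of 18 above the upper quartile of all values, immune genes 7.84 with 1 of 21, and endothelial genes 7.86 with 2 of 13, and their adjusted p with camera was 0.86, 0.93 and 0.86. The immune list's median (0.002) and mean (-0.002) differed in sign. The stomach or colon list had a mean difference of -0.039 (adjusted p = 0.061 with camera, 0.015 with fry for either direction). In it Prap1, an abundant intestinal secretory transcript, fell by 0.15 adjusted over the list alone, but not with the block (adjusted p = 0.11), with Onecut2 at -0.27, Cdx2 at 0.10 and Pgc at -0.08.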

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

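The fit of all probes was fixed beforehand, and the comparison of further with brightest probes was chosen after the results were seen. Several probes outside the table of 1 probe per gene passed limma's test over all probes. For 4 genes the further probe went the way of the gene's brightest probe: Arv1 (0.36 on the log2 scale, knockout minus control), Fcgrt (-0.30), Mtdh (0.54) and Zfhx3 (0.24). With the replicate block the adjusted p was 0.10 for Arv1, 0.13 for Fcgrt, 0.081 for Zfhx3 and 0.040 for Mtdh. There were also 3 probes with no gene or several genes, the largest rise being 1.94, from 7.81 ± 0.02 to 9.74 ± 0.05 (SD, n = 3). With the replicate block the smallest of these rises, 0.57, no longer passed limma's test (adjusted p = 0.061), while the others did.

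For 3 other genes the further probe and the brightest probe parted. A probe of Mcm6, a subunit of the replicative helicase, read 9.997 ± 0.15 in control and 7.88 ± 0.03 in knockout arrays (log2, SD, n = 3; difference -2.12). The gene's brightest probe differed by 0.02, and another bright probe, at a mean level of 10.3, by 0.07 (limma unadjusted p = 0.57). A probe of Tmem87a rose by 1.10 where the brightest differed by -0.48, and a probe of Ttpal fell by 0.48 where the brightest differed by 0.34. With the replicate block the Mcm6 and Tmem87a probes passed (adjusted p = 0.0050 each), and the Ttpal probe did not (0.074).

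A sequence variant under one probe could change its reading without any change in the transcript. Over all 7 genes, 4 brightest probes passed an unadjusted p of 0.05 in the direction of the further probe, which does not decide for the 7 as a set. These were the brightest probes of Arv1 (0.35), Fcgrt (-0.24), Mtdh (0.30) and Zfhx3 (0.17). For these 4 genes a variant under a single probe is argued against as the sole cause, although Arv1's probes lay near the bottom of the scale. For Mcm6, Tmem87a and Ttpal a variant under the probe and a change in 1 transcript form both stay open. The design gives the Snai1 genotype as the biological difference, and it was not tested apart from the background of the mice.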

How the results depend on the processing

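The 25 called genes depended on the model. There were 9 with the replicate block (all 9 among the 25), 60 with an intensity trend, 71 with a robust trend and 15 at a fold of at least 1.5. When all probes were tested, 40 probes passed, a count of probes that includes several of 1 gene and 3 with no gene or several. The count ranged from 4 to 23 when 1 array was left out: 6 without control replicate 1, 15 without control 2, 9 without control 3, 23 without knockout 1, 13 without knockout 2 and 4 without knockout 3. Repeating the quantile step, which moved almost nothing, centring on medians, cyclic loess, both filters on dim probes, the mean of a gene's probes and array weights gave 23 to 30. Erdr1 and Prkag2 passed in 18 of 18 alternatives and Ckap2 in 6 of 18. Lists called by camera numbered 2, against 8 with the replicate block, 5 with the mean of a gene's probes, 0 with an estimated correlation and 0 with fry. They ranged from 1 to 9 when 1 array was left out: 9 without control 2, 7 without knockout 1, 1 without knockout 2 and 6 without knockout 3. The stem cell list's adjusted p was 0.717 with an estimated correlation, 0.691 with fry and 1.64e-06 to 0.0774 without 1 array, the highest without knockout replicate 2. The p53 list's was 0.717 with an estimated correlation, 0.147 with fry and 0.0591 on ranks. Apart from fewer arrays and the fold threshold, the cause of these differences was not tested. Snai1 passed in no alternative. Camera on ranks and leaving out list members near called genes or genes on Snai1's chromosome were chosen after seeing the data, and the last left 21 called genes. Over the values followed through the alternatives, 2735 stayed on their side of the threshold, 32 moved past it, 79 fell short of it and 0 called values changed direction. Most of the values followed had not passed in the main fit, so staying mostly means that they still did not pass. The counts of genes and lists given above are not part of this tally. A floor before taking logs was not run, because the table was already on a log scale. Dim probes, compressed near 7.87, limit what could be seen.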

Other observations

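The tests on Snai1's chromosome, on neighbouring genes and on further probes were chosen after the results were seen. The estimated correlation was fixed beforehand, but what it would show was written down afterwards. Probes of the Y-linked genes Eif2s3y, Kdm5d and Uty read between 7.75 and 8.01 on all 6 arrays, while the brightest Xist probe read 10.3 to 11.4.

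The called genes clustered along the chromosomes. Of the 21 called genes not on Snai1's chromosome, 8 had another called gene among the 30 measured genes on either side, where 10000 draws matched on mean level gave 1.35 on average (permutation p = 0.0021). The pairs were Sema5a with Cmbl, Ip6k2 with Qrich1, Paip1 with Ccl28 and Prkag2 with 1500035N22Rik, where Qrich1 and Ccl28 are named only after their values were seen. Among genes with an unadjusted p under 0.001, 37 of 70 had such a neighbour against 14.5 drawn (permutation p = 1e-04, the smallest the draws can give). With the replicate block each of the 4 pairs lost at least 1 member, and 0 of 7 called genes on these chromosomes had a called neighbour, against 0.145 drawn, while at a blocked p under 0.001 it was 52 of 106 against 31.5 drawn (permutation p = 0.0007).

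As a hypothesis, blocks of DNA that differ between the parent mice may account for some of the called neighbours, since the clustering (permutation p = 0.0021) is what inherited blocks predict. The 21 called genes on other chromosomes lie outside any DNA linked to the Snai1 locus. Whether linked DNA affects them indirectly was not tested. For the 4 called genes on Snai1's chromosome, against 1.94 drawn, the count does not decide (permutation p = 0.127). The count covers the whole chromosome and takes no account of distance from Snai1. Linked DNA therefore stays open for these 4, all of them lower in the knockout. A variant under a single probe is argued against for the 5 called genes with a further probe above the upper quartile of all values. Each had one that moved the same way, although Nectin2, named after its values were seen, had another that differed by 0.06. For Erdr1 this was partly fixed in advance, since its further probe (7.80 in control, 9.01 in knockout) passed the cut only through its rise. Further probes of Ctse, Paip1, Sema7a and Sgip1 lay below the cut and none reached an unadjusted p under 0.05 (limma). Those of Ip6k2 also lay below the cut but rose, by 0.36 and 0.30 (limma unadjusted p = 0.00035 and 4.5e-06). Genes with further probes only below the cut were not judged. An effect of Snai1 loss on the called genes stays open. Genotype and parent line cannot be told apart in this design, where each group is 1 genotype. The labels do not give the background of the mice.

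No single array decided the call of the p53 list: the highest adjusted p without 1 array was 0.00962. Nor did Trp53inp1 and Bcl2l1, the members near called genes, since the adjusted p without them was 0.000584. Members that vary together within groups remain a possible explanation, because the call was lost with an estimated correlation (camera adjusted p = 0.717) and with fry (0.147). With an estimated correlation the unadjusted p was 0.053, the lowest of the 28 lists, none of which passed. The list's mean varied little within groups, however, with SD 0.022 in control and 0.028 in knockout (n = 3 each) against a difference of 0.106. The stem cell list's mean varied more, with SD 0.090 and 0.084 against a difference of 0.120. That list has the same adjusted 0.717 at an unadjusted p of 0.19. Cre acting on floxed alleles, which control organoids lack, could also engage p53, and no group here carries floxed alleles without loss of Snai1, so this was not tested.

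The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 25 genes and the highest other 1, so 1 of 10 splits gave as many. With the replicate block, 1 of the 4 splits that part all same-numbered pairs gave as many genes (9 in the real split, 0 at most in the others) and 1 of 4 as many lists (8 against 2). Without the block, 7 of 10 splits called as many lists as the real split's 2, and the highest called 11, grouping control replicates 1 and 3 with knockout replicate 3. That split keeps a same-numbered pair together, which points to a structure of the samples that follows the replicate numbers. The stem cell list passed in 3 of the 9 other splits, most strongly with control replicates 1 and 3 and knockout replicate 1 together (adjusted p = 3.2e-11), and 1 of these parted all pairs (adjusted p = 0.0058, and 0.0022 with the block). The p53 list passed in 1 other split (adjusted p = 0.0084), which does not part all pairs.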
